A study of Homo sapiens with 6 samples.

How the data were processed

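RNA was profiled from the human ovarian cancer cell line OVCAR-3 and from a carboplatin-resistant variant of it, per the labels, with 3 libraries of each, all taken at 24 h per the labels. Per the labels' protocols, both were grown in RPMI medium with fetal bovine serum, RNA was extracted with Trizol, and libraries were made with a stranded kit from Qiagen. The labels call the replicates biological, and nothing in them says how the cultures were split or how long the cells had been kept apart, so p-values measure only the spread between these samples. No pair of libraries in a group differed by as little as sampling noise (chi-square per degree of freedom 3.82 to 37.9), and each was counted as 1 replicate.

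The authors deposited raw counts of reads per Ensembl gene for 63241 genes. Per the submitters' processing notes, reads were assigned to genes with featureCounts 2.0.1 on hg38. The aligner, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Between 77.8% and 81.0% of the counts from 1 to 20 were even numbers, the pattern left when both mates of a read pair are counted, so a fragment can stand for more than 1 count. Genes encoded on the mitochondrial genome were listed at 0 counts in all 6 libraries, and no value is given for them.

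The authors also deposited a second table of CPM for 19635 genes, for which edgeR is named in the submitters' processing notes. In each library the ratio of raw count to CPM was a single constant, the effective library size, and 100.0% of the values came out as whole reads within 0.01 read. The count test on these recovered reads, added after the data had been seen, called 4422 genes higher and 4467 lower, as the raw counts did.

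Total counts per library lay between 41547068 and 58688409. Gene names were found for 62666 of the IDs. Positions came from GENCODE release 29 on GRCh38, the assembly that hg38 denotes, for 58228 of them. No columns of per-sample values were left unused.

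The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the raw counts of all 6 libraries with the group as the only term. Genes with low counts were removed by filterByExpr, TMM factors (0.98 to 1.02) scaled the libraries, and p-values were adjusted by the Benjamini-Hochberg method over the 19635 genes tested. Adjusted p under 0.05 counted as a call. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Levels are TMM-normalized CPM, given as mean ± SD over 3 libraries. A fold change reported as a ratio is 2 raised to the fitted log2 value.

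Before the data were examined, 49 lists of genes were written, covering adhesion, matrix, signalling, platinum response, stress, cell cycle, metabolism, immune genes, cell identity and markers of other cell types. Of these, 48 had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 48 lists. With a correlation estimated per list, none of the calls held. Camera then gave 4 lists higher and 1 lower at an unadjusted p under 0.05, while fry, which tests each list by itself, called 21 higher and 12 lower. The matrix protease list lost its call at an estimated correlation of -0.012, below the preset (adjusted p = 0.37 by camera). With an estimated correlation, camera takes p from the few residual degrees of freedom of the 6 libraries, so a call over 48 lists was hard to reach. A lost call therefore does not by itself show that correlation between genes had made it.

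Genes are named by a rule fixed at the same time. It takes FN1 and CDH1, the 8 largest increases and the 8 largest decreases among called genes with a mean of at least 5 CPM and groups that do not overlap, and up to 3 called members per described list with the largest change. Described lists are those called by camera and every adhesion, matrix and platinum list. For markers of other cell types the 3 most abundant members are named. Genes outside the rule were chosen after their values were seen, and the text says so. A gene that the rule names is not reported here.

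The fitting functions were tested on simulated counts for the 19635 genes, drawn from the real means, library sizes and dispersions with 200 changed genes in each of 5 runs. The test recovered 61.8% of genes changed 1.5-fold, 79.1% of genes changed 2-fold and 96.5% of genes changed 4-fold. False calls made up 4.96% of all calls. In the real data 45.27% of genes were called, so the adjustment was less strict there. The shares recovered in these runs therefore do not give the recovery of the real test. A list of 41 genes shifted 1.5-fold was called in 5 of 5 runs, and 0 of 235 tests of unshifted lists gave a call by camera. Each gene was drawn independently, whereas estimated correlations of the real lists reached 0.71. The runs therefore do not show how often camera miscalls lists of correlated genes.

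Alternatives fixed beforehand were DESeq2 size factors, library size alone and upper-quartile scaling, no filter and a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, limma on the deposited CPM with pseudocounts of 1 and 0.1 and without a filter, a block for the replicate number, each library left out in turn, and other set tests. Leaving out both libraries numbered 1 was added after the data had been seen. Gene neighbourhoods were examined among 14253 genes with a position and a mean of at least 1 CPM, using running medians of 51 genes, 1000 shuffles of the fold changes over the positions and, for trends with GC content and length, lowess from statsmodels 0.14.6. The minimum of 1 CPM was set when these computations were written, and the bounds of the MHC region, 28 and 34 Mb of chromosome 6, were set after the results had been seen.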

Results

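The data are RNA-seq counts from OVCAR-3, an established human cell line from high-grade serous ovarian cancer, and from a line resistant to carboplatin, a platinum drug that crosslinks DNA, which the labels call isogenic. The relation of the lines was not checked here. There were 3 parental and 3 resistant libraries. Total counts were 53297574, 49858333 and 53002446 for parental replicates 1 to 3 and 58688409, 43254009 and 41547068 for resistant replicates 1 to 3. The series title names fibronectin, E-cadherin and collective invasion of drug-resistant cells, so the comparison asks how transcript levels, those of adhesion and matrix genes among them, differ between resistant and parental cells.

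Resistant cells differed from parental cells in a large part of the transcriptome, with fibronectin and E-cadherin both higher. Of 19635 genes tested, 4422 were higher in resistant cells and 4467 were lower, and 1437 and 1508 of these differed more than 2-fold. FN1, which encodes fibronectin, a matrix glycoprotein bound by integrins, rose from 2556 ± 114 CPM to 10250 ± 1575 CPM (SD, n = 3), a 4.01-fold difference (log2 fold change 2.00, SE 0.10, adjusted p = 8.03e-10, edgeR). It took up 0.24% to 0.27% of all counts in parental libraries and 0.90% to 1.23% in resistant ones. CDH1, which encodes E-cadherin, the cadherin of epithelial adherens junctions, rose 2.04-fold, from 207 ± 4.9 CPM to 423 ± 51 CPM (SD, n = 3; log2 fold change 1.03, SE 0.09, adjusted p = 2.32e-07, edgeR). FN1 (ENSG00000115414) spans chromosome 2, 215360440 to 215436172, and CDH1 (ENSG00000039068) spans chromosome 16, 68737225 to 68835548, both protein-coding (GRCh38). The libraries of the groups did not overlap for either gene. They did not overlap for 54.0% of all tested genes, against 10% expected by chance for 3 against 3.

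Classical cadherins changed in opposite directions. Of 15 tested genes of adherens junctions and classical cadherins, 6 rose, 4 fell and 5 did not pass (7 and 5 when adjusted over the list alone). CDH6, which encodes K-cadherin, fell by 4.86 on the log2 scale (SE 0.14), from 450 ± 12 CPM to 15.4 ± 3.9 CPM. CDH2, which encodes N-cadherin, a usual marker of mesenchymal cells, fell by 3.31 (SE 0.12), from 198 ± 2.7 CPM to 19.8 ± 3.9 CPM. NECTIN3, a junctional adhesion molecule, fell by 1.39 (SE 0.14). Chosen after their values were seen, CDH3, which encodes P-cadherin, rose from 189 ± 5.6 CPM to 344 ± 11 CPM, and CTNNB1, which encodes the cadherin partner beta-catenin, fell from 951 ± 19 CPM to 565 ± 11 CPM. The list was not called (adjusted p = 0.83 by camera), and its median log2 fold change of 0.13 and its mean of -0.49 differed in sign.

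**Figure D1:**
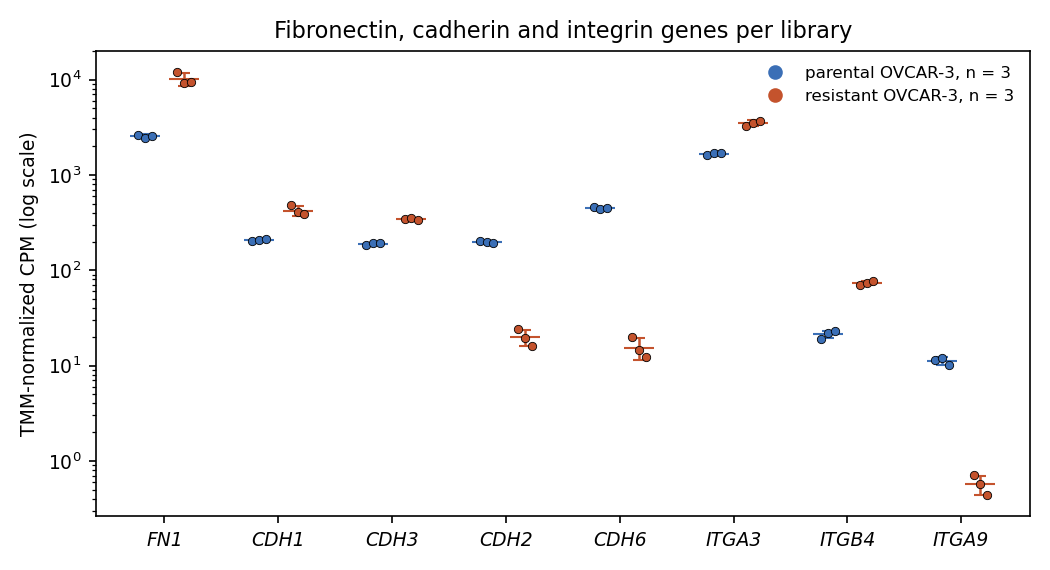
TMM-normalized CPM (log axis) of fibronectin, cadherin and integrin genes in 3 parental and 3 resistant libraries; points are libraries, and bars are the mean ± SD. FN1 rises from 2556 to 10250 CPM and CDH1 from 207 to 423 CPM, while CDH2 falls from 198 to 19.8 CPM and CDH6 from 450 to 15.4 CPM.

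Epithelial and mesenchymal markers each moved both ways. Among 36 tested epithelial identity and junction genes, 14 rose and 8 fell over all genes tested and adjusted over the list alone (adjusted p = 0.15 by camera). Beside CDH1, F11R, a tight junction protein, rose by 1.03 (SE 0.09) and MARVELD3, another tight junction protein, by 0.99 (SE 0.10). The keratin genes KRT8 and KRT18, chosen after their values were seen, fell from 7098 ± 456 to 4745 ± 277 CPM and from 3238 ± 172 to 2152 ± 225 CPM. Of 19 desmosome and hemidesmosome genes, 8 rose and 5 fell by both adjustments, the second being adjusted over the list alone (adjusted p = 0.27 by camera). ITGB4, the hemidesmosomal integrin subunit, rose by 1.79 (SE 0.09), LAMB3, a laminin chain, by 1.27 (SE 0.14) and PKP2, a desmosomal plaque protein, by 1.08 (SE 0.09). Of 21 mesenchymal markers and EMT transcription factors, 10 rose and 6 fell (11 and 7 adjusted over the list alone; adjusted p = 0.64 by camera). WNT5A, a Wnt ligand, fell by 2.94 (SE 0.13), whereas NT5E, which encodes CD73, rose by 2.30 (SE 0.09). VIM, which encodes vimentin and was chosen after its values were seen, was scarce and fell from 4.69 ± 0.76 to 1.51 ± 0.50 CPM. The median of the mesenchymal list was 0.35 and its mean -0.09.

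Fibronectin receptors and integrins were likewise mixed. Of 17 tested genes for fibronectin and its receptors, 9 rose and 4 fell by both adjustments, over all genes and adjusted over the list alone. Camera did not call this list (adjusted p = 0.11), whereas it passed on DESeq2 statistics (adjusted p = 0.0017) and with limma-voom (adjusted p = 0.039), within a range of 0.0017 to 0.54 for camera over the alternatives. Fry, which compares a list with no other genes, called it higher (adjusted p = 0.00011), as it did the epithelial (0.013), desmosome (0.010), integrin (0.00013) and actin (0.00091) lists. TGM2, a transglutaminase that crosslinks fibronectin, rose from 144 ± 12 to 830 ± 74 CPM (log2 fold change 2.53, SE 0.09), and ITGA9, an integrin subunit, fell by 4.26 (SE 0.18), from 11.2 ± 0.96 to 0.57 ± 0.13 CPM. Of 21 integrin subunits, 10 rose and 5 fell (10 and 6 adjusted over the list alone; adjusted p = 0.22 by camera), with a median of 0.30 and a mean of -0.04. ITGB4 again and ITGB2, with a log2 fold change of 1.40 (SE 0.11), were higher. Among genes chosen after their values were seen, ITGA3 rose from 1664 ± 46 to 3512 ± 233 CPM and ITGB1 from 474 ± 29 to 624 ± 36 CPM. ITGA5, the alpha subunit of the classical fibronectin receptor, was at 33.7 ± 1.3 and 29.6 ± 2.0 CPM and did not pass (adjusted p = 0.10). Of 46 actin cytoskeleton and focal adhesion genes, 24 rose and 13 fell by both adjustments, the second being adjusted over the list alone (adjusted p = 0.22 by camera). MYLK, a myosin light chain kinase, fell by 1.33 (SE 0.11), ACTN4, an actin crosslinker, fell by 0.91 (SE 0.07), and ZYX, a focal adhesion protein, rose by 0.89 (SE 0.08).

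Camera called the lists of matrix proteolysis, basement membrane and collagen processing higher, calls that did not hold with an estimated correlation (adjusted p = 0.37, 0.72 and 0.63), and did not call fibrillar matrix genes. Of 36 matrix proteases and inhibitors, 21 rose and 7 fell (21 and 8 adjusted over the list alone; adjusted p = 0.0033 by camera, and adjusted p = 0.37 with an estimated correlation). The kallikrein-related peptidases KLK5, KLK6 and KLK7 led the list. KLK5 rose from 2.75 ± 0.28 to 177 ± 18 CPM, KLK6 from 1.48 ± 0.29 to 52.0 ± 3.9 CPM and KLK7 from 1.95 ± 0.47 to 25.3 ± 3.5 CPM. Among members chosen after their values were seen, PLAU, which encodes urokinase, rose from 42.5 ± 3.1 to 133 ± 29 CPM. MMP15, a membrane-type matrix metalloproteinase chosen in the same way, rose from 22.8 ± 2.8 to 61.6 ± 1.7 CPM. Of 29 basement membrane genes, 17 rose and 3 fell (18 and 4 adjusted over the list alone; adjusted p = 0.018 by camera, and adjusted p = 0.72 with an estimated correlation). NTN4, which encodes netrin-4, rose by 1.95 (SE 0.15), COL4A6, a type IV collagen chain, by 1.54 (SE 0.10) and LAMB3 as above. The list's median fell from 0.30 to 0.18 when both libraries numbered 1 were left out. Of 19 collagen processing and crosslinking genes, 11 rose and 1 fell by both adjustments, the second being adjusted over the list alone (adjusted p = 0.025 by camera, and adjusted p = 0.63 with an estimated correlation). LOXL2, a lysyl oxidase, rose by 1.29 (SE 0.10), P4HA1, a prolyl hydroxylase subunit, by 0.87 (SE 0.09) and ADAMTS14, a procollagen peptidase, by 0.83 (SE 0.13). Of 32 fibrillar and interstitial matrix genes, 10 rose and 13 fell (12 and 13 adjusted over the list alone; adjusted p = 0.95 by camera). BGN, which encodes biglycan, rose by 2.59 (SE 0.09) and THBS1, which encodes thrombospondin-1, by 1.51 (SE 0.09), while CCN2, a matricellular growth factor, fell by 2.14 (SE 0.09), from 411 ± 3.7 to 93.3 ± 10.6 CPM.

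The largest differences lay in genes nearly silent in one of the lines. CCND2, which encodes cyclin D2, rose from 0.10 ± 0.06 to 33.7 ± 2.6 CPM (log2 fold change 8.33, SE 0.21). The other large increases, apart from KLK5 and KLK6, were BEND7 (5.23, SE 0.19), SLC2A3, a glucose transporter (4.98, SE 0.23), IFI27, an interferon-induced gene (4.55, SE 0.14), SLC18A3, a vesicular acetylcholine transporter (4.50, SE 0.18), and GJA5, a connexin (4.12, SE 0.16). EMX2, a homeobox transcription factor of urogenital development, had the largest decrease, from 21.2 ± 1.6 to 0.03 ± 0.03 CPM. Its 4 counts in all resistant libraries together, against 3325 in parental ones, put the ratio per total at 764-fold lower. With 2 counts taken as 1 read pair, which leaves 2 pairs in resistant libraries, the exact (Clopper-Pearson) 95% interval was 211 to 6310, for counting error only. LMO3, a LIM-domain protein, fell from 61.5 ± 6.5 to 0.23 ± 0.09 CPM, TMEM100 from 33.7 ± 3.7 to 0.30 ± 0.12 CPM and LGALS14, which encodes a galectin, from 61.8 ± 2.2 to 0.65 ± 0.10 CPM. DOK5 fell from 17.5 ± 2.5 to 0.20 ± 0.05 CPM, CHRNA9 from 14.5 ± 0.74 to 0.18 ± 0.10 CPM, ADGRL3 from 57.2 ± 1.2 to 0.76 ± 0.20 CPM and UNC5C from 88.8 ± 7.3 to 1.90 ± 0.42 CPM. Adjusted p for these 16 genes lay between 2.76e-13 and 4.13e-10 (edgeR). On the log2(CPM + 1) scale the changes of CCND2, BEND7, EMX2, DOK5 and CHRNA9 were smaller by more than 1.5 times, at 4.98, 3.43, -4.43, -3.94 and -3.72, with the direction kept.

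Camera called the MAPK output list higher and the Notch list lower, and neither call held with an estimated correlation (adjusted p = 0.46 and 0.63). Of 27 MAPK output genes, 21 rose and 4 fell (22 and 4 adjusted over the list alone; adjusted p = 7.93e-05 by camera, and adjusted p = 0.46 with an estimated correlation). DUSP4, a phosphatase induced by ERK, rose from 13.1 ± 0.86 to 130 ± 16 CPM. FOSL1, an AP-1 transcription factor, rose by 2.12 (SE 0.16) and ETV4, an ETS factor, by 1.64 (SE 0.11). Of 20 Notch targets and ligands, 2 rose and 10 fell (3 and 10 adjusted over the list alone; adjusted p = 0.027 by camera, and adjusted p = 0.63 with an estimated correlation). HEY1, a Notch target, fell by 3.82 (SE 0.17), JAG1, a Notch ligand, fell from 215 ± 7.0 to 29.2 ± 3.6 CPM, and DLL3, an inhibitory ligand, fell by 1.69 (SE 0.12). The Notch call was lost without parental replicate 2 (adjusted p = 0.067), within a range of 0.00011 to 0.63 for camera over its alternatives.

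Camera called targets of the unfolded protein response and ATF4 lower and cholesterol and heat shock genes higher, calls that did not hold with an estimated correlation (adjusted p = 0.39, 0.72 and 0.72). Of 29 such ATF4 and unfolded protein response genes, 19 fell and 4 rose by both adjustments, the second being adjusted over the list alone (adjusted p = 0.0033 by camera, and adjusted p = 0.39 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, fell by 1.90 (SE 0.10), SLC7A11, the cystine transporter, fell by 1.34 (SE 0.11) and STC2, which encodes a stanniocalcin, fell by 1.25 (SE 0.08). HERPUD1, which acts in degradation of proteins from the endoplasmic reticulum and was chosen after its values were seen, rose from 39.6 ± 0.74 to 85.9 ± 4.6 CPM. Of 24 genes of cholesterol biosynthesis and uptake, 17 rose and 2 fell (19 and 3 adjusted over the list alone; adjusted p = 0.0072 by camera, and adjusted p = 0.72 with an estimated correlation). Among enzymes of the pathway, MVD rose by 1.18 (SE 0.10) and TM7SF2 rose from 51.2 ± 6.2 to 110 ± 8.4 CPM. Of 14 heat shock genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.018 by camera, and adjusted p = 0.72 with an estimated correlation). BAG3, a chaperone partner, rose by 0.96 (SE 0.08), HSPB8 by 0.83 (SE 0.14) and HSPH1 by 0.49 (SE 0.07). Of 30 replication-dependent histone genes, 13 fell and none rose over all genes tested (12 and 0 adjusted over the list alone; adjusted p = 0.0042 by camera, and adjusted p = 0.63 with an estimated correlation). The log2 fold changes of H2BC21, H2AC6 and H4C8 were -0.96 (SE 0.09), -0.92 (SE 0.08) and -0.81 (SE 0.14). Histone genes are near-identical copies whose mRNAs mostly lack poly(A) tails, so their counts are uncertain. The median of this list was -0.74 and came to -0.46 on the log2(CPM + 1) scale and to -0.29 there without a filter. On the latter scale the Notch median was -0.24.

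Antigen presentation and interferon response genes were the lists with the lowest p by camera, both higher. Of 21 antigen presentation genes, 19 rose and none fell (20 and 0 adjusted over the list alone; adjusted p = 1.97e-08 by camera, and adjusted p = 0.38 with an estimated correlation), with a median log2 fold change of 1.11. HLA-B, an MHC class I heavy chain, rose from 107 ± 7.6 to 438 ± 68 CPM, HLA-F, a non-classical class I gene, by 2.09 (SE 0.14) and NLRC5, the class I transactivator, by 1.76 (SE 0.11). Chosen after their values were seen, HLA-C rose from 360 ± 30 to 753 ± 59 CPM and B2M, which encodes the light chain beta-2 microglobulin, from 313 ± 13 to 546 ± 26 CPM. Class I genes resemble one another, and how shared reads were counted is not given in the sources used here. Of 41 type I interferon response genes, 28 rose and 3 fell (28 and 4 adjusted over the list alone; adjusted p = 1.02e-06 by camera, and adjusted p = 0.37 with an estimated correlation). IFI27 rose from 1.98 ± 0.10 to 46.5 ± 8.0 CPM, BST2, which encodes tetherin, from 6.26 ± 0.67 to 74.9 ± 8.7 CPM and IFI6 from 8.39 ± 2.25 to 54.1 ± 8.2 CPM.

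Markers of leukocytes were scarce in both lines, and the summed level of 8 tested markers was 13.99 CPM in parental and 19.1 CPM in resistant cells. Of these, 2 rose and 0 fell over all genes and adjusted over the list alone (edgeR), with CORO1A at 5.23 ± 0.74 and 5.26 ± 0.64 CPM, CD14 rising from 2.39 ± 0.23 to 7.07 ± 0.39 CPM, and LCP1 at 2.95 ± 0.08 and 2.15 ± 0.61 CPM, which did not pass (adjusted p = 0.073). LCP1 passed as lower with limma-voom and without resistant replicate 3 (log2 fold change -0.71, adjusted p = 0.0087), within a range of 0.0087 to 0.23. Of 6 mesothelial markers, 3 rose and 1 fell (3 and 2 adjusted over the list alone, edgeR). CALB2, which encodes calretinin, rose from 33.3 ± 1.7 to 161 ± 27 CPM and MSLN, which encodes mesothelin, from 32.1 ± 2.3 to 83.3 ± 11.4 CPM, while the keratin gene KRT5 fell from 133 ± 7.4 to 78.7 ± 2.6 CPM. Of 8 endothelial markers, 5 rose and 2 fell, also when adjusted over the list alone. EGFL7 rose from 44.0 ± 4.5 to 73.8 ± 9.96 CPM, KDR fell from 31.0 ± 1.3 to 4.18 ± 0.10 CPM, and ERG was at 8.58 ± 0.83 and 8.81 ± 0.40 CPM. Of 5 fibroblast markers, 1 rose and 1 fell (2 and 1 adjusted over the list alone), with FBLN1 at 440 ± 5.7 and 427 ± 32 CPM, COL1A1 at 27.7 ± 3.9 and 28.2 ± 3.5 CPM, and COL1A2 falling from 3.59 ± 0.46 to 2.05 ± 0.43 CPM. Of 10 neural and neuroendocrine markers, 1 rose and 3 fell, also when adjusted over the list alone, with SYT1 at 15.1 ± 2.4 and 13 ± 0.53 CPM, ENO2 at 9.10 ± 1.03 and 8.54 ± 0.77 CPM, and NCAM1 falling from 13.7 ± 1.3 to 5.77 ± 0.95 CPM. Camera called none of these 5 lists (adjusted p = 0.22 to 0.71). Fry called leukocyte (adjusted p = 0.0029), mesothelial (0.0024) and fibroblast (0.044) markers higher and neural ones lower (0.028), but not endothelial ones (0.48). CALB2, MSLN and KRT5 are also known from carcinoma cells.

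Camera called none of the 7 lists tied to platinum handling and DNA repair (adjusted p = 0.22 to 0.83). Fry called homologous recombination, mismatch repair and translesion synthesis genes lower (adjusted p = 0.028 each) and metallothioneins higher (adjusted p = 0.024). The metallothionein list had a median of 0.22, and the medians of its members' neighbours within 5 Mb had a median of 0.84. Of 32 genes of platinum uptake, efflux and sequestration, 13 rose and 10 fell by both adjustments, the second being adjusted over the list alone, with a median of 0.12 and a mean of -0.01. ABCG2, a drug efflux pump, rose from 2.47 ± 0.45 to 29.3 ± 3.5 CPM. GSTM4, a glutathione transferase, fell by 2.16 (SE 0.12) and LRRC8D, a volume-regulated channel subunit through which platinum drugs enter cells, fell by 0.81 (SE 0.09). Among transporters chosen after their values were seen, SLC31A1, the copper importer CTR1, had a log2 fold change of 0.28 (SE 0.09, adjusted p = 0.016). That call was lost without parental replicate 2 (0.23), without parental replicate 3 (0.29) and without resistant replicate 3 (0.28), and adjusted p ranged from 0.0063 to 0.11. ATP7B, a copper exporter, rose by 0.54 (SE 0.14) but stood at 0.30 and did not pass with both libraries numbered 1 left out (adjusted p = 0.055, range 0.00042 to 0.055). ABCB1, the P-glycoprotein gene, was at 1.24 ± 0.11 and 1.07 ± 0.47 CPM and did not pass (adjusted p = 0.55).

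Among 6 metallothionein genes and their regulators, 2 rose and 2 fell (3 and 2 adjusted over the list alone). MT2A, a metal-binding protein, rose from 427 ± 78 to 1630 ± 185 CPM, MTF1, the metal-responsive transcription factor, fell by 0.64 (SE 0.08) and SLC30A1, a zinc exporter, fell by 0.47 (SE 0.09). Of 35 NRF2 targets and glutathione genes, 12 rose and 11 fell (13 and 11 adjusted over the list alone), with a median of 0.12 and a mean of -0.04. The members with the largest changes and at least 5 CPM were all lower: AKR1B10 fell by 2.07 (SE 0.15), SLC7A11 fell as above and HMOX1, the heme oxygenase gene, fell by 0.94 (SE 0.12). Of 27 nucleotide excision repair genes, 5 rose and 3 fell (5 and 2 adjusted over the list alone). ERCC6 rose by 0.69 (SE 0.08), ERCC2 rose by 0.57 (SE 0.08) and XPC fell by 0.58 (SE 0.09). ERCC1, chosen after its values were seen, rose from 28.7 ± 1.9 to 36.7 ± 1.9 CPM. Of 47 homologous recombination and Fanconi anaemia genes, 3 rose and 14 fell by both adjustments, the second being adjusted over the list alone. TP53BP1 fell by 0.87 (SE 0.09), FANCD2 fell by 0.80 (SE 0.08) and BRIP1 fell by 0.68 (SE 0.12). BRCA1, chosen after its values were seen, fell by 0.25 (SE 0.08, adjusted p = 0.018), and did not pass without parental replicate 3 (-0.23) or without resistant replicate 3 (-0.22), with adjusted p from 0.0019 to 0.090. Of 16 mismatch repair genes, 3 rose and 4 fell (1 and 4 adjusted over the list alone), among them PMS2 (-0.59, SE 0.08), MSH3 (-0.58, SE 0.09) and RFC4 (-0.44, SE 0.09). Of 13 translesion synthesis genes, 1 rose and 6 fell by both adjustments, the second being adjusted over the list alone, among them HLTF (-0.76, SE 0.13), USP1 (-0.66, SE 0.08) and REV3L (-0.57, SE 0.13).

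**Figure D2:**
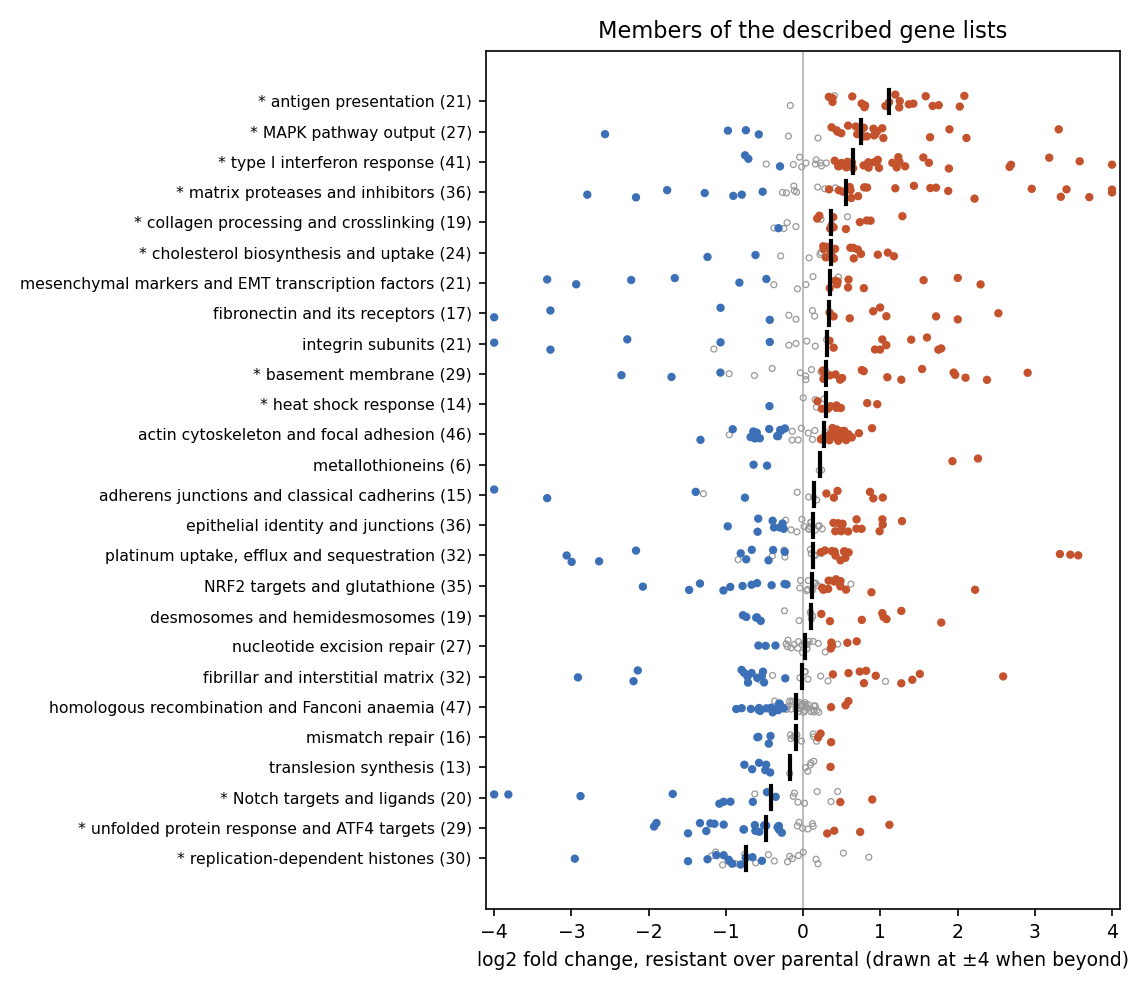
Log2 fold change, resistant over parental, of each tested member of the described lists, with the number tested in brackets; filled points passed adjusted p under 0.05 by edgeR, open points did not, black bars are medians, an asterisk marks lists called by camera, and members beyond 4 in size are drawn at the edge. Antigen presentation has the highest median, 1.11, and replication-dependent histones the lowest, -0.74.

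Fold changes also depended on where a gene lies. Running medians over 51 genes were taken among 14253 genes with a position and a mean of at least 1 CPM. At some positions they went beyond the highest of 1000 shuffles (0.42 in size). The 51-gene windows centred there, joined where windows of the same direction overlapped, formed 17 regions holding 18.9% of the genes. A region thus also holds genes at its edges whose own running median did not go beyond 0.42. Genes were higher between 30.7 and 90.0 Mb of chromosome 16 (median log2 fold change 0.59; 243 of 327 higher and 11 lower), from 0.1 to 28 Mb (0.49) and from 43.4 to 87.0 Mb (0.44) of chromosome 10, and from 140.7 to 144.5 Mb of chromosome 8 (0.40). The other 13 regions were lower. They included 3 that together covered much of chromosome 3 (-0.54, -0.48 and -0.42), 22.8 to 74.7 Mb of chromosome 15 (-0.56; 211 of 285 lower and 17 higher), 0.2 to 13.5 Mb of chromosome 11 (-0.62) and 24.0 to 42.2 Mb of chromosome 19 (-0.75).

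**Figure D3:**
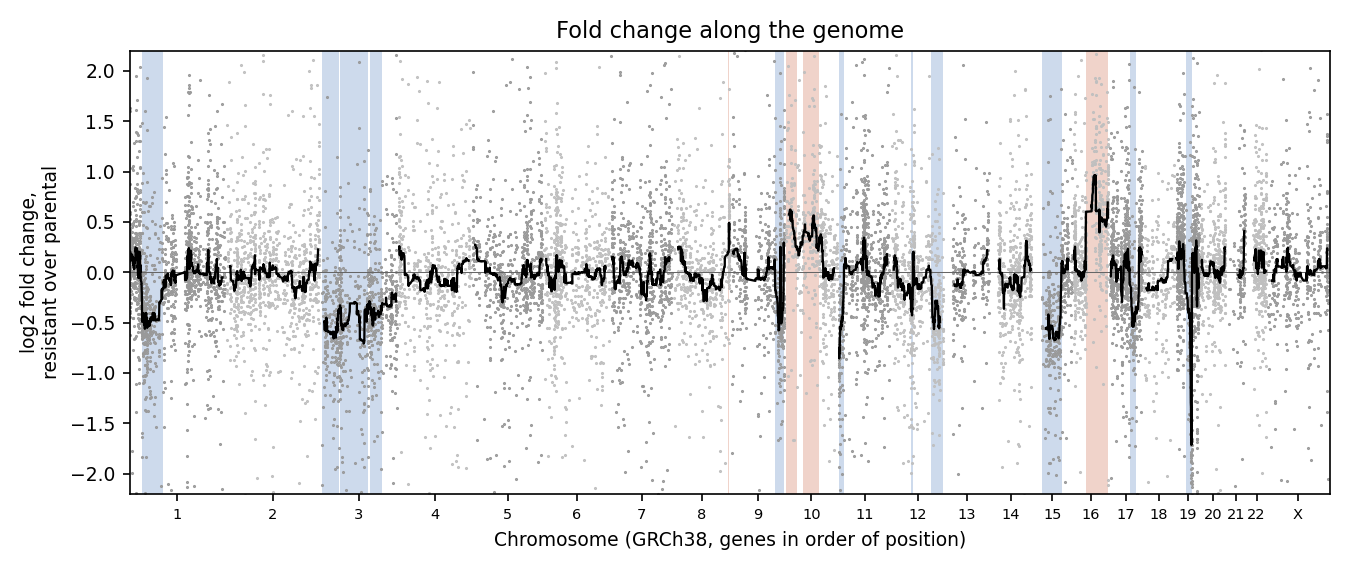
Log2 fold change, resistant over parental, along the genome. Gray points are genes, and the black line is the running median of 51 genes. Shading marks the joined 51-gene windows whose median went beyond the highest of 1000 shuffles (red higher, blue lower). The points beyond 2.2 in size lie outside the axis, and the line reaches its lowest value, -1.71, on chromosome 19.

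Several genes named above lie in such regions. CDH1 is on the long arm of chromosome 16, where 115 tested neighbours within 5 Mb had a median log2 fold change of 0.51, and its own value of 1.03 was above that of 87.0% of them. FN1 is in no such region. Its 51 neighbours had a median of 0.09, and FN1 was above 98.0% of them. Neighbour medians were 0.84 around MT2A and NLRC5, 0.86 around MMP15, 0.84 around HERPUD1, 0.51 around CDH3, 0.53 around MARVELD3 and CALB2, and 0.67 around MVD, all on chromosome 16. They were 0.48 around P4HA1 and ADAMTS14, 0.49 around ERCC6 and SLC18A3, 0.57 around BEND7 and 0.54 around PLAU, all on chromosome 10, against a drop in VIM on the same chromosome, whose neighbours had a median of 0.50. Around ACTN4, DLL3 and LGALS14 between DPF1 and SERTAD3 on chromosome 19 they were -0.69, -0.59 and -0.58. These flanks run past the ends of that block, whose edges were chosen after the values were seen. Within it the median of 53 genes with at least 5 CPM was -1.59, against -0.91 for ACTN4, -1.69 for DLL3 and -6.55 for LGALS14. Neighbour medians were -0.54 around XPC, -0.57 around FANCD2, -0.61 around ITGA9, -0.73 around NECTIN3, -0.51 around WNT5A, -0.47 around CTNNB1 and -0.43 around HLTF, all on chromosome 3. On other chromosomes they were -0.47 around MTF1, -0.42 around BRIP1, -0.37 around USP1 and -0.46 around TMEM100. KRT8, KRT18 and KRT5 lie in a lower region of chromosome 12 (49.8 to 53.4 Mb, median -0.43). Within 5 Mb their neighbour medians were -0.16, -0.18 and -0.21. Around TP53BP1 and CHAC1 on chromosome 15 they were -0.50 and -0.53. B2M and THBS1 lie on the same part of chromosome 15, with neighbour medians of -0.54 and -0.60, and rose. Of genes named further below, KIF2C on chromosome 1 and AMOTL2 on chromosome 3 lie in lower regions and fell, with neighbour medians of -0.51 and -0.45. WNT7A on chromosome 3 and AXL on chromosome 19, with neighbour medians of -0.555 and -0.425, lie in lower regions too and rose.

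**Figure D4:**
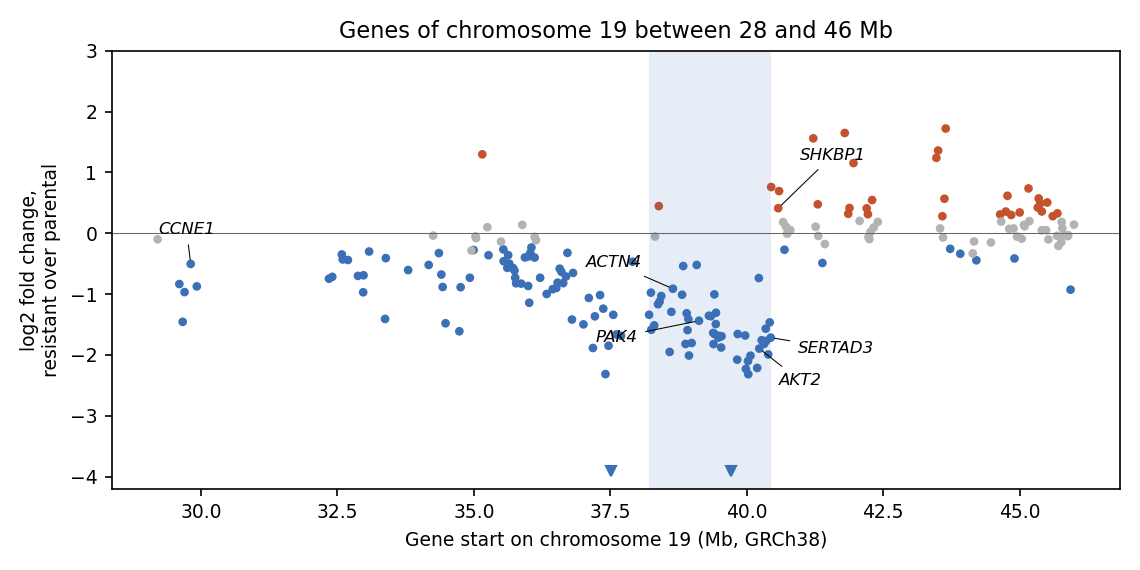
Log2 fold change, resistant over parental, of genes with a mean of at least 5 CPM against their start on chromosome 19 (Mb, GRCh38); colored points passed adjusted p under 0.05 by edgeR (red higher, blue lower), gray points did not, and triangles are genes below -4. In the shaded block from 38.21 to 40.44 Mb, 50 of 53 genes are lower, with a median of -1.59.

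The annotation leaves some of these values open. The strand setting of the counting is not given in the sources used here, so whether genes on opposite strands were told apart is open. Exons on the other strand overlapped 31.1% of the exonic bases of PLAU, 30.4% of XPC, 28.7% of TP53BP1, 28.6% of ERCC1, 28.5% of HLA-F, 24.4% of VIM, and 20.3% each of KLK6 and GJA5. The share was 27.5% for ALDH1A3, which is named further below. Exons of another gene on the same strand overlapped 36.6% of F11R and 13.8% of CCND2. The metallothionein, glutathione transferase and MHC class I genes are families of close copies, among which reads can be split. KLK5, KLK6 and KLK7 also belong to a gene family and lie side by side between 50943303 and 50984099 of chromosome 19, in a single locus.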

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

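No pairing by replicate number was visible: deviations of same-numbered libraries from their group means correlated at 0.0287, 0.0408 and -0.0313 across genes. Libraries with different numbers gave -0.0674 to 0.0388. Whether same-numbered cultures were handled together is not given in the labels. With the replicate block, 4507 genes were higher and 4612 lower, FN1 stood at 1.99 and CDH1 at 1.02, and no call of a named gene or described list changed. Under all alternatives, 0 of 2850 values of 150 named genes and 0 of 546 values of described lists turned direction with a call on either side. Turns without a call in both the main test and the alternative were not counted. Fry gave such turns for the adherens junction, platinum uptake and fibrillar matrix lists. Of the lists, 12 values lost their call, 11 of them with an estimated correlation, and 11 gained one; of the genes, 6 values lost and 2 gained a call. Genes more than 2-fold higher and lower numbered 890 and 971 with a filter of 1 CPM in 3 libraries, which tested 14791 genes. They numbered 592 and 689 with limma on log2(CPM + 1), 805 and 880 on log2(CPM + 0.1), both with 14584 genes tested, and 606 and 730 on log2(CPM + 1) without a filter. Filter, pseudocount and test changed together in the first 2 of these, and their shares were not separated. Lists higher numbered 13 with DESeq2 statistics, for which the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower, and with fry, which compares no list with other genes, 21 and 12. Leaving out each library in turn gave 3743 to 4797 genes higher, 3797 to 5049 lower, 1401 to 1451 more than 2-fold higher, 1431 to 1713 more than 2-fold lower, 8 lists higher, 2 to 3 lower, 1.87 to 2.07 for FN1 and 0.93 to 1.097 for CDH1. Without both libraries numbered 1, a setting chosen after the data had been seen, 4783 genes were higher and 5030 lower, with 91.7% of the reported calls among them. Simulated 1.5-fold changes were called in 61.8% of genes with 200 genes changed per run, a share that need not hold for the real test. A gene without a call is not shown to be level.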

Other observations

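The genes named in this part were chosen after their values were seen, and so were the edges of the chromosome 19 block and the tests of immune cells and of 1 resistant library standing apart. Several fixed lists that camera did not call held large changes. Of 38 hypoxia and glycolysis genes, 15 rose and 10 fell (16 and 11 adjusted over the list alone; adjusted p = 0.22 by camera). EPAS1, which encodes the hypoxia factor HIF-2 alpha, rose from 64.7 ± 0.89 to 257 ± 31 CPM and EGLN3, a hydroxylase induced by hypoxia, from 17.2 ± 1.8 to 84.5 ± 10.1 CPM. HK2, a hexokinase, fell from 309 ± 24 to 127 ± 16 CPM. Of 24 Wnt targets and regulators, 6 rose and 13 fell, as many as when adjusted over the list alone (adjusted p = 0.22 by camera). LEF1, a transcription factor of the pathway, fell from 22.5 ± 1.3 to 1.60 ± 0.12 CPM, and WNT7A, a ligand, rose from 5.25 ± 0.44 to 50.7 ± 5.8 CPM. Of 34 NF-kB targets and inflammatory cytokines, 19 rose and 12 fell (19 and 12 adjusted over the list alone; adjusted p = 0.16 by camera), with CXCL16 rising from 13.5 ± 0.21 to 95.5 ± 1.4 CPM, LCN2 from 31.2 ± 1.6 to 123 ± 9.3 CPM, and CXCL1 falling from 107 ± 14 to 40.5 ± 10.7 CPM. Of 25 YAP and TEAD targets, 12 rose and 5 fell (12 and 5 adjusted over the list alone; adjusted p = 0.11 by camera). AXL, a receptor tyrosine kinase, rose from 29.2 ± 2.2 to 86.1 ± 12.9 CPM and AMOTL2 fell from 639 ± 36 to 273 ± 24 CPM. Of 25 TGF-beta targets, 10 rose and 11 fell (10 and 11 adjusted over the list alone; adjusted p = 0.83 by camera; median -0.23, mean 0.04).

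Camera called neither the mitosis nor the DNA replication list. Of 40 mitosis and G2/M genes, 4 rose and 15 fell (4 and 16 adjusted over the list alone; adjusted p = 0.12 by camera), with KIF2C falling from 139 ± 1.8 to 72.2 ± 2.3 CPM and TOP2A rising from 293 ± 13 to 412 ± 8.1 CPM. Of 44 DNA replication genes, 13 rose and 8 fell (13 and 8 adjusted over the list alone; adjusted p = 0.52 by camera). Ovarian identity genes were mixed, with 7 higher and 8 lower of 25 (7 and 8 adjusted over the list alone; adjusted p = 0.83 by camera). MUC16, which encodes the CA-125 antigen, rose from 31.8 ± 2.3 to 99.5 ± 36.2 CPM. Of 22 stem cell and chemoresistance markers, 7 rose and 10 fell (7 and 10 adjusted over the list alone; adjusted p = 0.52 by camera), with ALDH1A3 rising from 94.2 ± 7.7 to 204 ± 8.9 CPM and SOX2 falling from 188 ± 11 to 105 ± 11 CPM. Of 17 squamous and mucinous markers, 5 rose and 10 fell (5 and 11 adjusted over the list alone; adjusted p = 0.25 by camera). Counts of higher and lower genes were 13 and 8 of 32 for apoptosis regulators, 10 and 8 of 27 for p53 targets, 7 and 3 of 20 for immediate early genes, 7 and 5 of 15 for senescence and CDK inhibitors, 8 and 9 of 27 for fatty acid genes, 8 and 16 of 66 for the nuclear-encoded respiratory chain, and 13 and 25 of 76 for cytosolic ribosomal proteins. These 7 pairs of counts were the same when adjusted over the list alone, and none of these lists was called by camera (adjusted p = 0.22 to 0.95). Of 177 families of genes that share a symbol root, formed after the data had been seen, 0 were called by camera after adjustment, while the intraflagellar transport genes came first, with 10 of 15 lower and 0 higher (unadjusted p = 0.00064 and adjusted p = 0.11 by camera).

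The steepest regional difference is on chromosome 19, in a block that holds AKT2, a kinase gene known to be amplified in some ovarian cancers. From DPF1 to SERTAD3 (38211006 to 40444705), 50 of 53 genes with at least 5 CPM were lower in resistant cells and 2 were higher, with a median log2 fold change of -1.59 (quartiles -1.82 and -1.29). AKT2 fell from 1836 ± 139 to 494 ± 13 CPM, PAK4 from 540 ± 39 to 199 ± 2.4 CPM, RPS16 from 9601 ± 766 to 3413 ± 345 CPM and SERTAD3 from 204 ± 6.3 to 62.1 ± 2.9 CPM. In the 2 Mb from SHKBP1 onward, 11 of 27 genes were higher and 2 lower, with a median of 0.18, and SHKBP1 itself rose from 29.1 ± 1.6 to 38.7 ± 2.8 CPM. The median gene of the block was at 163 CPM in parental and 62.1 CPM in resistant cells, and that of the next region at 33.2 and 37.8 CPM. From POP4 to the block, 69 of 79 genes were lower and 1 higher, with a median of -0.69, among them CCNE1, which encodes cyclin E1 and fell from 184 ± 6.1 to 130 ± 10 CPM.

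Neighbouring genes shifted together, and differences in the copy number of large segments between the cell populations are a candidate explanation. Across genes, which are not independent replicates, the Spearman correlation of fold changes was 0.1459 for pairs 2 to 10 Mb apart, against at most 0.0038 in 1000 shuffles, as that explanation needs. Adjacent genes correlated more strongly (0.3655), but co-regulation or shared reads of adjacent genes alone would leave no correlation at 2 to 10 Mb. After trends with GC content and transcript length were removed, 0.1356 remained, 92.9% of the value, so these do not account for it. No DNA was measured here, and regional changes in chromatin remain open.

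Camera called antigen presentation and interferon response genes higher, though not with an estimated correlation (adjusted p = 0.38 and 0.37), and 3 technical explanations were examined. The summed CPM of the 8 tested leukocyte markers rose by 0.335% of the rise of the antigen presentation genes. The cutoff for this share was set after the data had been seen. ITGB2, a leukocyte integrin subunit outside that list, rose from 7.79 ± 0.55 to 20.6 ± 2.4 CPM. The listed markers thus gave little sign of immune cells, but a small share of such cells in the cultures is not excluded. List members outside chromosome 6 were higher by a median of 0.7156 (34 of 48 higher, 3 lower), and 154 other genes between 28 and 34 Mb of chromosome 6 had a median of 0.06, so extra copies of the MHC region would not account for the pattern. Under the 3 other scalings the lowest median of the antigen presentation list was 1.1014 against 1.1136. These scalings moved the median of all genes only between -0.0133 and 0.0058, so they could not have changed the list's median by much. A biological difference between the lines, in interferon signalling for example, remains a hypothesis that these data do not test further.

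Resistant libraries differed more from each other than parental ones, with a biological coefficient of variation of 0.119 against 0.074. Depth is argued against, because after thinning to 1 total the ratio was 1.636, against 1.601 before. Resistant replicates 2 and 3 alone gave 0.0725, within the range of the parental pairs (0.0362 to 0.088), but parental replicate 1 also stood furthest from its group, and parental replicates 2 and 3 gave 0.0362. Whether resistant replicate 1 accounts for the difference in spread is therefore left open. Whether the libraries numbered 1 shared a day or a batch is not given in the labels.

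The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes higher, lower, more than 2-fold higher and more than 2-fold lower, 1 split gave a count as large, the real one, at 4422, 4467, 1437 and 1508, and the highest of the other splits was 0. Every other split mixed both lines in each group, so the difference between lines became spread within groups. That 0 therefore does not measure a chance level. For lists called by camera with the preset correlation, 2 splits gave 8 or more higher, with 8 as the highest of the others, and against the 3 lists lower of the real split, all 10 gave 3 or more in their larger direction, with 8 as the highest.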
